A study of Mus musculus with 40 samples.

How the data were processed

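The deposited table holds raw counts of reads per gene for 40 lane files, with 32544 gene rows named by symbol. Per the labels, libraries were made from liver RNA with a TruSeq kit. The genome build was GRCm38, per the submitters' processing notes. The aligner, the counting tool, the annotation and the strand setting are not given in the sources used here, so how reads shared by near-identical or overlapping genes were counted is open, and values of single members of such families are uncertain. All values are whole counts and no column was left unmapped.

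The 2 lane files of each mouse come from the same library. They were checked with a chi-square test over genes with at least 20 reads: chi-square per degree of freedom was 1.33 to 1.49 between lanes of a mouse, and at least 10.1 between mice of a group. All 20 mice had their own lanes as the best correlated pair. Lanes thus differed slightly more than sampling noise, most in pseudogenes and in Mup2, but far less than mice did, and they were summed. In 1 file the treatment label says vehicle while its title says VB. Its other lane, which the title also places in VB, matched it as the same library, and the mouse was kept as a VB mouse.

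Groups come from the titles, with 5 mice in each of 4 groups, and p-values measure the spread between mice. The analysis used R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and sva 3.50.0. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 12616 genes holding 99.95% of counts. Counts were scaled by TMM factors, and all 4 groups were fitted together with edgeR's robust quasi-likelihood model. The 6 contrasts were VB on each diet, diet in each treatment, the difference of the VB effects and their mean. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Log2 CPM used a prior count of 2, and CPM in the text are on TMM-scaled library sizes.

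The tests, the 40 gene lists and the rule for named genes were fixed before the data were examined. The rule takes fixed genes in every comparison, of which 19 are reported. In each comparison of a pair of groups it adds the 10 called genes with the largest rise and the 10 with the largest fall, among named genes whose groups do not overlap and whose mean is at least 1 CPM in the higher group. It adds up to 4 called members of each list with the smallest p and, for the difference of VB effects, the 10 genes with the smallest p. A few genes that the rule names are not reported here; they stayed in all fits and lists. Lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, which left 38, and again with an estimated correlation and with fry. Fry tests whether genes of a list move 1 way on balance and does not compare it with other genes.

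The procedure was tested on simulated counts in which genes were changed by known folds in the VB comparison on control diet. Over 12465 genes, 24 of 49 genes changed 1.5-fold were recovered, 38 of 49 changed 2-fold, 47 of 50 changed 3-fold and 43 of 48 changed 4-fold, and 6 unchanged genes were called. Depth of 16315342 counts or more per mouse sets counting error, while the spread between mice was the larger error. Gene positions come from GENCODE on GRCm38, where 12275 of 12616 tested symbols were found.

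Alternatives were other scaling (RLE, upper quartile), DESeq2, limma-voom with and without quality weights, other filters, fits of only the groups compared, the mouse number as a block, single lanes, lanes as samples, a surrogate variable, a fold minimum of 1.5 and leaving out each mouse. Added after seeing the data were the clock score as a covariate and Mup genes left out of library sizes. For each count 100 splits of the mice were fitted, the real one included.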

Results

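RNA of mouse liver was sequenced from germ-free male C57BL/6 mice, which carry no gut microbes, at postnatal day 64 after 6 weeks of treatment. The treatment was delta-valerobetaine (VB), a trimethylated compound made by gut bacteria, or vehicle. Mice ate a control diet or a Western diet, which gave 4 groups of 5 mice. The design asks what VB does in the liver on each diet, and whether its effect depends on the diet. Each of the 20 mice had 2 lane files of the same library, which were summed to 1 replicate. Summed counts ran from 18126657 to 21308298 per mouse in control diet vehicle mice and from 19762505 to 23202394 in control diet VB mice. They ran from 16315342 to 22226536 in Western diet vehicle mice and from 18157449 to 24566686 in Western diet VB mice. In all, 12616 genes were tested.

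Circadian clock genes differed between groups, and this stands beside every comparison that follows. A clock score, the first principal component of the clock list scaled to an SD of 1, averaged -1.39 ± 0.45 (SD, n = 5) in control diet vehicle mice and -0.09 ± 0.26 in control diet VB mice. It averaged 0.30 ± 0.42 in Western diet VB mice and 1.18 ± 0.12 in Western diet vehicle mice. The ranges of the VB groups overlapped, while those of the vehicle groups lay outside them. Of the variance of the score, 90.4% lay between groups. The labels give no collection time. Library names also differed in form between the diets, so any handling batch that follows them could not be separated from diet.

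**Figure D1:**
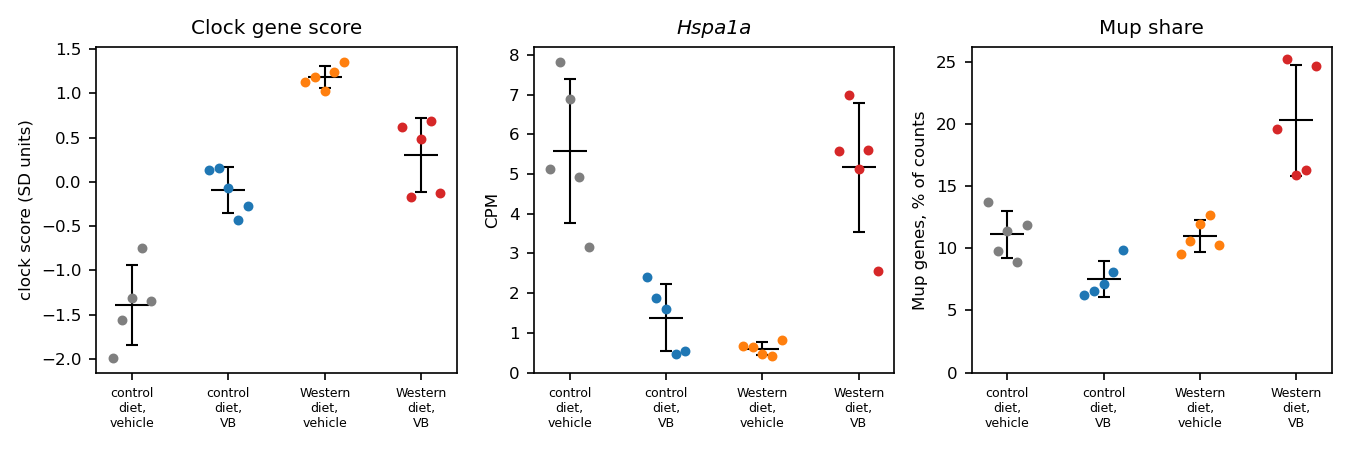
Clock gene score (SD units), Hspa1a (CPM) and the share of counts in Mup genes (percent) are drawn for each mouse as points, with the mean and SD of the 5 mice of each group. The vehicle groups lie at the ends of the clock score, at means of -1.39 and 1.18, and Western diet VB mice have the highest Mup share, at 20.3%.

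The first question was what the Western diet changed in vehicle mice. Genes of cholesterol synthesis fell together, while a part of the lipid droplet and sterol export genes rose. Members of the fatty acid oxidation list rose as well, but that list was not called with an estimated correlation. Sqle, which encodes squalene epoxidase of cholesterol synthesis (chromosome 15, 59315077 to 59331192 on the plus strand, GRCm38), fell 86.6-fold, from 97.6 CPM ± 16.3 to 1.09 ± 0.48 (SD, n = 5). Cidec, which encodes a lipid droplet protein (chromosome 6, 113424634 to 113435760, minus strand), rose 35.6-fold, from 2.08 CPM ± 0.82 to 74.2 ± 49.96. In edgeR's quasi-likelihood test 2083 genes changed, 1125 of them higher and 958 lower.

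Of 25 tested members of the cholesterol synthesis and uptake list, 23 fell and none rose, or 24 and none when adjusted over the list alone. The log2 changes were -6.44 (SE 0.29) for Sqle, -4.52 (SE 0.16) for Idi1 and -3.81 (SE 0.15) for Cyp51. The list stood apart from other genes with a preset correlation in camera (adjusted p = 1.82e-47) and with an estimated one (adjusted p = 0.00685). In the list of LXR targets and sterol export, 6 of 12 members rose and 1 fell, the same counts as when adjusted over the list alone. The sterol exporters Abcg5 and Abcg8 rose by 1.83 (SE 0.17) and 1.48 (SE 0.17) on the log2 scale, and the list held with an estimated correlation (adjusted p = 0.0497). Among lipogenic genes 7 of 22 fell and none rose, or 8 when adjusted over the list alone, with Fasn at -1.92 (SE 0.44) and Acly at -1.91 (SE 0.39). That call was not kept with an estimated correlation (adjusted p = 0.563).

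Of 20 lipid droplet and fatty liver genes 13 rose and none fell, or 14 when adjusted over the list alone (adjusted p = 0.0293 with an estimated correlation). Cidea rose by 5.74 (SE 0.97), Apoa4 by 3.19 (SE 0.36), and the fatty acid receptor Cd36 and the adipogenic regulator Pparg by 1.79 each (SE 0.32 and 0.23). Of 28 PPARA targets 17 rose and none fell, or 20 when adjusted over the list alone, among them Vnn1 at 2.08 (SE 0.36). Of 20 genes of mitochondrial fatty acid oxidation 13 rose, also when adjusted over the list alone, including Cpt1a at 0.91 (SE 0.15). With an estimated correlation both of these lists had an adjusted p of 0.347. Of 12 carnitine genes 5 rose, or 6 higher and 1 lower when adjusted over the list alone, with the carnitine transporter Slc22a5 at 1.08 (SE 0.23) and Bbox1, the last enzyme of carnitine synthesis, at 0.34 (SE 0.09). That list's adjusted p was 0.553 with an estimated correlation.

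Clock genes changed widely. Of 21, 11 rose and 6 fell, the same when adjusted over the list alone, with Dbp at 4.80 (SE 0.68), Per3 at 3.21 (SE 0.33), Npas2 at -4.98 (SE 0.48) and Nfil3 at -1.76 (SE 0.16). The adjusted p was 0.347 with an estimated correlation. Of 26 acute phase genes 15 rose and 1 fell, or 15 and 4 when adjusted over the list alone, with Orm3 at 3.13 (SE 0.38) (adjusted p = 0.459 with an estimated correlation). Of 16 heat shock genes 6 fell, the same when adjusted over the list alone, with Hspa1a at -3.17 (SE 0.39) and Dnajb1 at -0.96 (SE 0.15) (adjusted p = 0.553 with an estimated correlation). Cfd, which encodes the adipokine adipsin, rose from 0.93 CPM ± 0.50 to 167.1 ± 93.9 (SD, n = 5). It belongs to the adipose tissue list, in which 2 of 6 tested members rose, the same when adjusted over the list alone (adjusted p = 0.459 with an estimated correlation).

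With the clock score as a covariate, chosen after seeing the data, 39 genes changed with diet in vehicle mice instead of 2083. Of the 2083, 1664 kept their sign, their median absolute log2 change went from 0.60 to 0.42 and their median SE from 0.14 to 0.43. The medians of the fatty acid oxidation, carnitine, PPARA, acute phase, clock, endoplasmic reticulum stress, ribosomal, male-biased and female-biased lists then took the opposite sign, while that of cholesterol synthesis kept its sign. Of the genes named above, Cd36 (-0.0752), Slc22a5 (-0.0441), Bbox1 (-0.16) and Dbp (-1.20) also took the opposite sign, and none of the 4 passed with the covariate. Dbp and the clock list make up the score itself, so their change with it carries little weight.

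**Figure D2:**
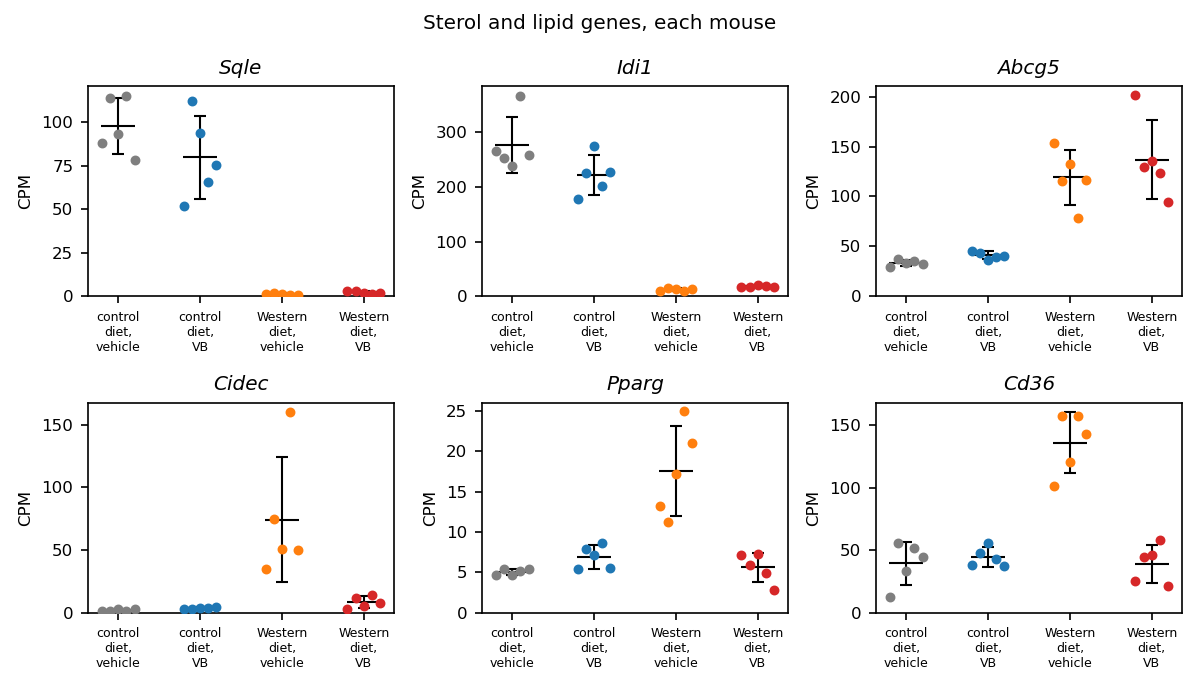
CPM of Sqle, Idi1 and Abcg5 (sterol genes) and of Cidec, Pparg and Cd36 (lipid genes) are drawn for each mouse as points, with the mean and SD of the 5 mice of each group. Sqle lies near 1.09 CPM in Western diet vehicle mice and near 97.6 CPM in control diet vehicle mice, and Cidec is highest in Western diet vehicle mice.

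The next question was what VB changed on the Western diet. Lipid droplet genes were lower in VB mice, with either correlation in camera. A part of the PPARA targets, carnitine genes and drug-metabolizing genes was lower too, and a part of the male-biased, heat shock and cholesterol synthesis genes was higher, but none of those lists was called with an estimated correlation. Fry, which does not compare a list with other genes, called 10 of the 16 lists called with the preset correlation. Cidec fell 8.76-fold, from 74.2 CPM ± 49.96 to 8.42 ± 4.55 (SD, n = 5). Slc22a5, which encodes the carnitine transporter OCTN2 (chromosome 11, 53864542 to 53891660, minus strand, GRCm38), fell 2.38-fold, from 43.7 CPM ± 8.68 to 18.4 ± 3.25. In all 907 genes changed, 420 of them higher and 487 lower.

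Of 20 lipid droplet genes 11 fell and 1 rose, or 16 and 1 when adjusted over the list alone. The log2 changes were -3.13 (SE 0.42) for Cidec, -4.65 (SE 0.87) for Cidea, -1.64 (SE 0.22) for Pparg, -1.79 (SE 0.32) for Cd36 and -0.62 (SE 0.12) for the droplet coat gene Plin2. Of the lists called in this comparison it alone held with an estimated correlation (adjusted p = 0.0334). Of 28 PPARA targets 17 fell and none rose, or 22 when adjusted over the list alone, with Abcd2 at -1.91 (SE 0.30). Their adjusted p was 0.113 with an estimated correlation.

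Of 20 fatty acid oxidation genes 10 fell and none rose, or 14 when adjusted over the list alone, including Acadm at -0.66 (SE 0.12) and Hadh at -0.55 (SE 0.11) (adjusted p = 0.139 with an estimated correlation). Of 12 carnitine genes 5 fell, or 6 when adjusted over the list alone. Slc22a5 was at -1.25 (SE 0.23), the acetyltransferase gene Crat at -0.65 (SE 0.18), Slc25a20 at -0.52 (SE 0.12) and Bbox1 at -0.33 (SE 0.09). The carnitine list had an adjusted p of 0.256 with an estimated correlation. Tmlhe and Aldh9a1, earlier enzymes of carnitine synthesis, did not pass the test, at -0.24 (SE 0.11) and -0.15 (SE 0.08).

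Of 31 xenobiotic metabolism genes 16 fell and 1 rose, or 21 and 1 when adjusted over the list alone. Cyp3a11 changed by -1.54 (SE 0.24), Por by -0.95 (SE 0.16) and Cyp2b9 by -6.76 (SE 1.25). The adjusted p was 0.113 with an estimated correlation. Members of the Cyp2 and Cyp3 families share sequence, and their single values are uncertain where reads match several of them. Of 25 cholesterol synthesis genes 10 rose, or 15 when adjusted over the list alone, with Insig1 at 1.26 (SE 0.24) and Mvd at 1.33 (SE 0.25) (adjusted p = 0.233 with an estimated correlation). Sqle did not pass, at 1.02 (SE 0.32).

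Of 20 male-biased liver genes 15 rose and none fell, or 17 and 1 when adjusted over the list alone. Elovl3 rose by 1.26 (SE 0.22) and Hsd3b5 by 1.38 (SE 0.22), and Moxd1 by 4.89 (SE 1.19). Of 9 female-biased genes 3 fell, or 4 when adjusted over the list alone. Both lists had an adjusted p of 0.113 with an estimated correlation. Of 6 adipose genes 3 fell and 1 rose, the same when adjusted over the list alone, with Cfd at -3.20 (SE 0.57), and the list was not called (adjusted p = 0.196 with the preset correlation). Mup genes, which encode major urinary proteins and share long stretches of sequence, took 20.3% ± 4.46 of counts in VB mice on this diet (SD, n = 5) and from 9.53% to 12.7% in the 5 vehicle mice.

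Of 16 heat shock genes 8 rose, the same when adjusted over the list alone, with Hspa1a at 3.05 (SE 0.39), its near-identical copy Hspa1b at 2.70 (SE 0.41) and Dnajb1 at 1.08 (SE 0.15) (adjusted p = 0.161 with an estimated correlation). Of 20 endoplasmic reticulum stress genes 6 rose, or 7 when adjusted over the list alone, with Herpud1 at 0.96 (SE 0.17) (adjusted p = 0.491 with an estimated correlation). Tat, a glucocorticoid-induced enzyme of tyrosine breakdown, rose by 1.98 (SE 0.26). Of 21 clock genes 4 rose and 4 fell, or 4 and 6 when adjusted over the list alone, with Nfil3 at 1.31 (SE 0.16), Arntl at 1.84 (SE 0.35) and Wee1 at -1.92 (SE 0.32). The clock list was not called (adjusted p = 0.78 with the preset correlation).

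With the clock score as a covariate 11 genes changed with VB on the Western diet. Of the 907 genes 906 kept their sign, while their median absolute log2 change went from 0.61 to 0.48 and their median SE from 0.14 to 0.20, so calls ended through both a smaller change and a larger error. Of the 16 lists called with the preset correlation 14 stayed called with it, 1 lost its call and 1 changed sign. With only both groups compared in the fit 464 genes changed. Western diet vehicle mouse 4 stood apart from its group, with 4.62% of counts from mitochondrially encoded genes, and without it 1225 genes changed.

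VB changed few genes on the control diet. The circadian repressor gene Ciart (chromosome 3, 95878503 to 95882251, minus strand, GRCm38) rose 6.70-fold, from 1.29 CPM ± 0.59 to 8.70 ± 4.21 (SD, n = 5), and Hspa1a fell 3.99-fold, from 5.58 CPM ± 1.82 to 1.38 ± 0.85. In all 19 genes changed, 7 of them higher (36.8%) and 12 lower, and 1354 had an unadjusted p under 0.05. Clock genes were among them, with Tef at 1.12 (SE 0.20) and Npas2 at -1.93 (SE 0.36) on the log2 scale. Slc9a9, which encodes a sodium-proton exchanger, changed most of those that fell, at -3.77 (SE 0.62), from 1.96 CPM ± 0.61 to 0.14 ± 0.11. Bnip3, Upp2, Tgm1 and Sec22c rose, and Clk1, Cited2, Rnf125, Hist1h1c, Cdk20, Phospho1 and Acrbp fell.

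No carnitine, fatty acid oxidation, PPARA or lipid droplet gene passed the test over all genes on this diet. With the preset correlation their lists were called higher, opposite to the Western diet, at median log2 changes of 0.14, 0.0963, 0.18 and 0.17. With an estimated correlation each had an adjusted p of 0.629. Without control diet vehicle mouse 1 the carnitine list, at 0.0452, and the lipid droplet list, at 0.0735, also lost their calls with the preset correlation. Slc22a5 was at 0.40 (SE 0.23), Bbox1 at 0.08 (SE 0.09), Cpt1a at 0.56 (SE 0.15) and Cidec at 0.80 (SE 0.50). Of 21 clock genes 2 rose and 1 fell, or 9 and 3 when adjusted over the list alone (adjusted p = 0.0951 with an estimated correlation). Of 20 male-biased genes none passed over all genes and 8 fell when adjusted over the list alone (adjusted p = 0.343 with an estimated correlation). Of the 15 lists called with the preset correlation none held with an estimated one, and fry called 1 of the 15. The count was 164 in DESeq2, 29 with upper-quartile scaling (48.3% of them higher), 66 without control diet vehicle mouse 5 (63.6% of them higher), 6 without mouse 1 and 11 without mouse 3 of that group, 10 without control diet VB mouse 3 and 8 without its mouse 4. It was 0 in edgeR with the clock score as a covariate. Of the 19 genes 18 kept their sign, while their median absolute log2 change went from 0.86 to 0.67 and their median SE from 0.16 to 0.25. The exception was Npas2 (0.26), a clock gene that is part of the score, so its turn carries little weight. Of the 15 called lists 4 stayed called, 5 lost their call and 6 changed sign, among them the carnitine, fatty acid oxidation, PPARA and male-biased lists.

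The test of the difference between the VB effects on the diets called 964 genes, 458 of them higher and 506 lower for Western relative to control diet. Lipe, which encodes hormone-sensitive lipase, differed by -1.89 (SE 0.19), Pparg by -2.09 (SE 0.32), Cidec by -3.93 (SE 0.64), Slc22a5 by -1.65 (SE 0.32) and Cpt1a by -1.06 (SE 0.21). Hspa1a differed by 5.05 (SE 0.53), its co-chaperone gene Bag3 by 1.59 (SE 0.19) and the clock repressor Nfil3 by 1.98 (SE 0.23). Of 20 male-biased genes 18 differed upward, the same when adjusted over the list alone (adjusted p = 0.0795 with an estimated correlation). Of 28 PPARA targets 16 differed downward, or 23 when adjusted over the list alone (adjusted p = 0.107 with an estimated correlation). Of 21 clock genes 4 differed upward and 9 downward, or 5 and 10 when adjusted over the list alone (adjusted p = 0.193 with an estimated correlation). Without Western diet vehicle mouse 4 the count was 1702. With the clock score as a covariate edgeR called 0, against 1300 in DESeq2 without that covariate and 2605 genes with an unadjusted p under 0.05 in the reported fit. Of the 964 genes 869 kept their sign with the covariate, while their median absolute log2 difference went from 0.84 to 0.52 and their median SE from 0.20 to 0.40. Of the 15 called lists 4 stayed called, 8 lost their call, the male-biased and PPARA lists among them, and 3 changed sign, the clock list among them. The score is made from the clock list, so the turn of that list carries little weight.

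Averaged over diets, VB changed 20 genes, 6 of them higher and 14 lower. A change in this mean can come from a single diet and does not show a change on both. The aminotransferase genes Tat and Got1 rose by 1.01 (SE 0.18) and 0.51 (SE 0.09) on the log2 scale, and the detoxification genes Ephx1 and Ugdh changed by -0.39 each (SE 0.08 for both). None of the 19 genes fixed beforehand and reported here passed. The count was 0 without Western diet VB mouse 2, where DESeq2 called 176 in all mice and 1292 genes had an unadjusted p under 0.05 in edgeR. It was 65 without mouse 4 and 11 without mouse 3 of that group. Without Western diet vehicle mice 1, 2, 3 and 5 in turn it was 42, 13, 13 and 33, without control diet VB mice 1, 2 and 4 it was 5, 13 and 10, and without control diet vehicle mouse 2 or 4 it was 8. With the clock score as a covariate it was 97.

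In VB mice the Western diet still lowered cholesterol synthesis genes and raised a part of the sterol export genes, and lipid droplet genes did not change as a list. In all 813 genes changed, 407 of them higher and 406 lower. Of 25 cholesterol synthesis genes 21 fell, or 22 when adjusted over the list alone, with Sqle at -5.12 (SE 0.26), a 34.9-fold fall (adjusted p = 0.0107 with an estimated correlation). Of 12 LXR targets 5 rose and 1 fell, the same when adjusted over the list alone, with Abcg5 at 1.74 (SE 0.17) (adjusted p = 0.0372 with an estimated correlation). Of 20 lipid droplet genes 2 rose and 2 fell, or 4 and 3 when adjusted over the list alone. Cidec did not pass, at 1.23 (SE 0.44), nor did Pparg, at -0.31 (SE 0.23).

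Of 31 xenobiotic genes 13 fell and 1 rose in VB mice, or 18 and 1 when adjusted over the list alone, with Cyp2b10 at -5.52 (SE 0.55) and Cyp2c29 at -1.60 (SE 0.15) (adjusted p = 0.258 with an estimated correlation). Of 20 male-biased genes 11 rose, or 13 higher and 1 lower when adjusted over the list alone, with Mup7 at 2.20 (SE 0.28) (adjusted p = 0.265 with an estimated correlation). Of 7 MHC class II genes 4 fell, the same when adjusted over the list alone, with H2-Ab1 at -0.96 (SE 0.18) (adjusted p = 0.404 with an estimated correlation). Of 6 adipose genes 2 rose, or 3 when adjusted over the list alone, with Cfd at 4.05 (SE 0.69) (adjusted p = 0.265 with an estimated correlation). None of 8 red blood cell genes passed in edgeR, over all genes or when adjusted over the list alone, though the list was called higher with the preset correlation (adjusted p = 0.698 with an estimated one). Without control diet VB mouse 4 the count was 541, with the clock score as a covariate it was 737, and in limma-voom with quality weights it was 1421.

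**Figure D3:**
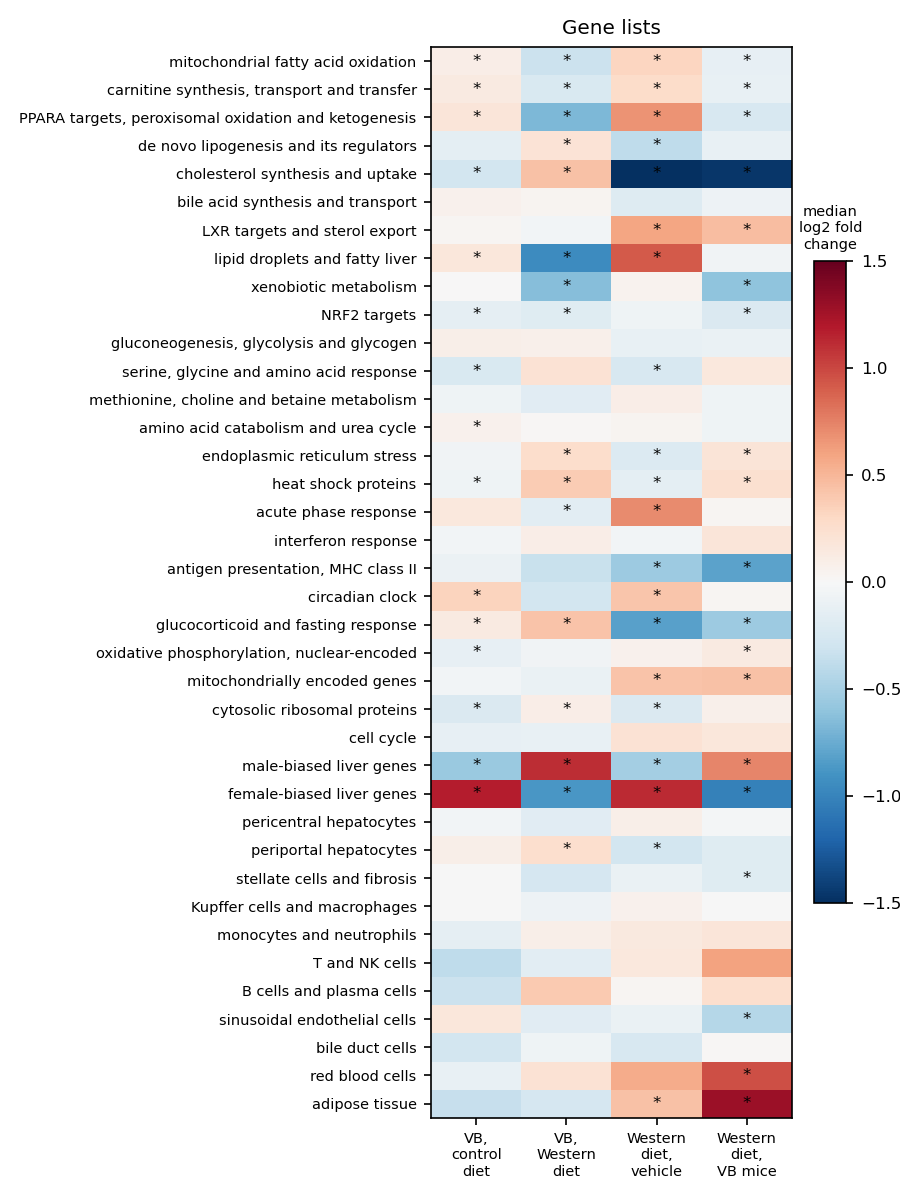
Median log2 fold change of each tested gene list (rows) in 4 comparisons (columns) is drawn as colour, red for higher and blue for lower, limited at -1.5 and 1.5, and a star marks an adjusted p under 0.05 in camera with the preset correlation. The lipid droplet list lies at 0.92 for Western diet in vehicle mice and at -0.94 for VB on the Western diet.

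The comparisons were then set against each other across the 12616 genes, which are not independent replicates. In the simulations used here each gene was drawn independently. They therefore lack any variation that the genes of a mouse share, and their spread of r can be too narrow. The VB effects on the diets share no mouse, and their log2 changes correlated at r = -0.27 (jackknife SE over mice 0.0976, Spearman's rho = -0.24) against 0.00031 on average for 20 simulations of unchanged groups. This r was -0.0430 with no filter on low counts and -0.40 over genes above the median expression. Of the 907 genes called on the Western diet 710 had the opposite sign on the control diet. The diet effects in vehicle and VB mice correlated at r = 0.28 (jackknife SE over mice 0.106, rho = 0.23) against -0.00426 simulated. This r was 0.0824 with no filter and 0.39 over genes above the median expression. These effects shared 123 genes that rose, where independent lists would share 36.3, and 168 that fell, where they would share 30.8.

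Genes that rose with the Western diet in vehicle mice and fell with VB on that diet numbered 373, and 286 did the reverse. The log2 changes correlated at r = -0.65 (jackknife SE over mice 0.0821, rho = -0.62), and at -0.53 with no filter. Both comparisons use the Western diet vehicle mice, which favours such overlaps and alone gave r = -0.50 on average in the 20 simulations. The covariance was -0.150, against -0.0350 simulated. With those mice split between the comparisons in 20 ways, r averaged -0.37, from -0.47 to -0.26, and the covariance averaged -0.108.

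**Figure D4:**
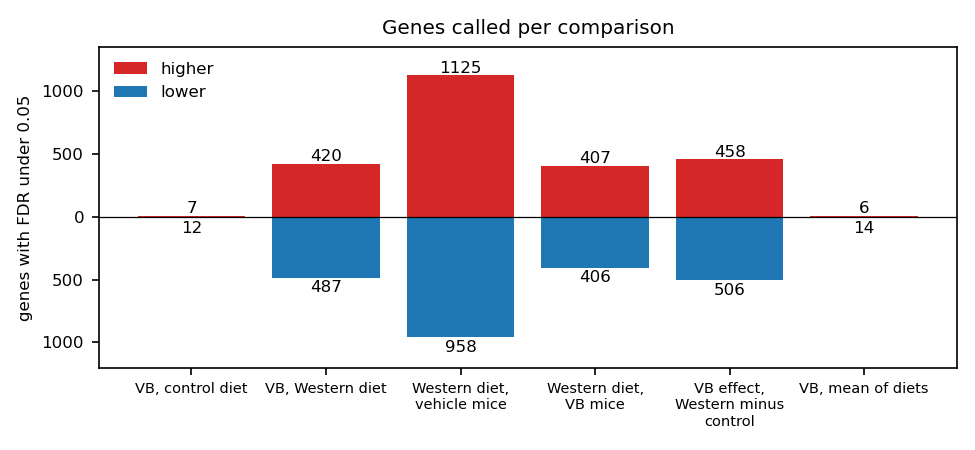
Genes with an adjusted p under 0.05 in edgeR are drawn as bars for each comparison, higher above 0 and lower below it. Western diet in vehicle mice has the most, 1125 higher and 958 lower, and VB on the control diet has 7 higher and 12 lower.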

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

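The tests on Western diet vehicle mouse 4, on Mup copies, on genes taking many counts and on Hspa1a with Hspa1b were chosen only after the result was seen. A mouse was marked when its gap to the nearest mouse of its group exceeded 0.71 of the group's range. That happened in 14 of 264 groups of 5, and chance marks about 1 in 20 groups.

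Western diet vehicle mouse 4 had 25.0% of counts in its 10 highest genes and 4.62% in mitochondrially encoded genes, and a mean log2 CPM of 11.06 in the mitochondrially encoded list and 6.72 in the LXR list. In the same group mouse 5 had an interferon list mean of 3.11 and mouse 3 had Fgf21 at 2.74 CPM. Western diet VB mouse 3 had a TMM factor of 0.995, and mouse 5 a T and NK cell list mean of 1.13. In control diet VB mice, mouse 2 had an LXR list mean of 6.77, and mouse 4 an interferon list mean of 2.52. In control diet vehicle mice, mouse 1 had list means of 3.95 for lipid droplets and 6.19 for the acute phase, mouse 2 had Scd1 at 11194 CPM, and mouse 5 had Cyp7a1 at 37.1 CPM.

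The VB effect differed between the diets, Western minus control, for 964 genes by the test of the difference in edgeR. The log2 differences of fixed genes that passed were -0.42 for Bbox1, -1.65 for Slc22a5, -1.06 for Cpt1a, -0.85 for Crat, -3.93 for Cidec, -0.54 for Plin2, -1.96 for Cd36, -2.09 for Pparg and 1.31 for Sqle. Those with the smallest p were -1.89 for Lipe, -2.22 for Fzd4, 5.05 for Hspa1a, -1.34 for Sec22c, 1.98 for Nfil3, 1.59 for Bag3, -2.12 for Gpcpd1, 1.41 for Ddc, -3.02 for Abcd2 and 1.08 for Proser2.

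Called lists had median log2 differences of -0.44 for fatty acid oxidation, -0.39 for carnitine, -0.82 for PPARA targets, 0.26 for lipogenesis, 0.70 for cholesterol synthesis, -1.25 for lipid droplets and -0.63 for xenobiotic metabolism. They were 0.29 for the serine and amino acid response, 0.33 for endoplasmic reticulum stress, 0.37 for heat shock, -0.35 for the acute phase, -0.41 for the clock, 0.31 for ribosomal proteins, 1.58 for male-biased and -1.34 for female-biased genes. None of these 15 lists was called with an estimated correlation, and fry called 11 of the 15.

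Chance assignment of mice was tested by counting calls in 100 splits, the real one included. The real split gave the most genes for VB on the control diet (19, highest other 2), VB on the Western diet (907, highest other 501), diet in vehicle mice (2083, highest other 102), diet in VB mice (813, highest other 4) and the difference of VB effects (964, highest other 172), 1 split each. For the mean VB effect (20, highest other 27) 2 splits gave as many. At a share under 0.05, chance can be excluded for each comparison of a pair of groups. For the difference and the mean, labels were exchanged within each diet. Such splits ask only whether VB had no effect on either diet. They do not test whether the effects differ between the diets or whether an effect is shared by both. Chance is therefore not excluded for these readings.

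The first pattern weighed was the VB changes on the Western diet. Of the 907 calls 781 stayed called without Western diet vehicle mouse 4, which argues against that mouse as the whole source. Clock phase at collection may contribute: of 899 called genes outside the clock list, 77.8% had the slope on the clock score within groups that the group difference needs, against a median of 50.4% and a 95th percentile of 73.4% in 10000 permutations. As 90.4% of the score's variance lay between groups, a shift of the clock caused by VB or diet and a different hour of collection cannot be told apart. The VB treatment itself stays among the open explanations.

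The second pattern was the rise of male-biased genes with VB on the Western diet. Shuffling of reads between Mup copies would leave their sum equal, but the summed share differed (exact permutation p = 0.00794, two-sided). A few genes taking most counts would scale all other genes of a mouse alike. The 14 tested members without Mup in their name rose by 1.32 in mean log2 CPM against the median of all other genes of the same mouse (exact permutation p = 0.00794, two-sided), which argues against that explanation for these members. The clock phase, which was tested on all 899 genes (77.8%), may also bear on these genes. Within groups the mean of the 20 tested male-biased genes correlated with the clock score at r = -0.62 (rho = -0.57). That is the sign their rise needs, as the score was lower in VB mice on this diet. With the score as a covariate the male-biased list stayed called higher for VB on the Western diet with the preset correlation. It lost its call in the test of the difference. The clock phase stays open beside VB treatment.

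The third pattern was that heat shock genes responded to VB differently on the diets: 8 of 16 rose on the Western diet, and on the control diet only Hspa1a passed, and fell. Reads shared between Hspa1a and Hspa1b would leave other members unmoved, but 4 others (Hspa8, Hsph1, Dnajb1 and Fkbp4) were higher in the test of the difference. Handling stress at death could not be judged: 19 immediate-early genes had a median log2 difference of -0.0413 (camera p = 0.665), with members going both ways. The prediction set beforehand, that a median of 0 or below would exclude it, was wrong, because such a median decides nothing. VB treatment stays open, and so does the clock phase, as the clock score differed between vehicle and VB mice in opposite directions on the diets. With that score as a covariate the test of the difference called 0 genes, but the median SE of the 964 genes went from 0.20 to 0.40. That count therefore says little about heat shock genes. Their list stayed called in that fit with the preset correlation. Within groups the mean of the 16 heat shock genes correlated with the score at only r = 0.03.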

How the results depend on the processing

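The clock score covariate and the removal of Mup genes were chosen only after the data were seen; all other alternatives were planned. Over all alternatives 10637 values of named genes were counted as kept, 717 lost their call and 87 gained one. Genes not called in the reported fit counted as kept when their sign changed, so the 10637 need not all have kept their direction. Of values of called lists 2769 kept direction and call, while 277 lost the call. Counting lanes as mice is not a valid test and is given to show its effect. Except where fewer mice or genes were used, the cause was not tested. Depth limits genes of few counts, and between-mouse spread limits small folds: 24 of 49 genes changed 1.5-fold were recovered in the simulated VB comparison on control diet.

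VB on the control diet (19 genes) gave 29 with upper-quartile scaling, 164 in DESeq2, 40 in limma-voom, 261 with quality weights, 29 at 1 CPM in 5 mice, 66 with only both groups fitted, 36 with lane 2, 998 with lanes as samples, 47 with a surrogate variable and 0 with the clock score. The higher share, 36.8%, was 48.3% with upper-quartile scaling, 51.2% in DESeq2, 53.3% with quality weights, 58.3% with lane 2, 63.1% with the replicate block and 63.6% without control diet vehicle mouse 5, and at the lowest 25.0% without control diet VB mouse 5, so the balance of directions is open. VB on the Western diet (907) gave 483 at a fold of 1.5, 464 with only both groups, 2653 with lanes as samples, 1411 with a surrogate variable and 11 with the clock score. Diet in vehicle mice (2083) gave 1066 at that fold, 3958 with lanes as samples and 39 with the clock score. Diet in VB mice (813) gave 474, 1421 with quality weights and 2929 with lanes as samples. The difference of VB effects (964) gave 1661 with quality weights, 2754 with lanes as samples and 0 with the clock score in edgeR. The mean VB effect (20) gave 11 at that fold, 176 in DESeq2, 106 with quality weights, 946 with lanes as samples, 106 with a surrogate variable and 97 with the clock score.

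The correlation of VB effects (-0.27) was -0.40 over genes above the median expression, -0.0430 with no filter and -0.45 with the clock score. That of diet effects (0.28) was 0.39, 0.0824 and 0.47, and that of diet in vehicle mice with VB on the Western diet (-0.65) was -0.53 with no filter. Both effects share a fitted slope when the clock score is a covariate. Unchanged simulated groups then gave -0.59 on average for VB effects, from -0.61 to -0.55. For diet effects they gave 0.39, from 0.35 to 0.43. The value of -0.45 was less negative than in any of these simulations, and that of 0.47 was above them all. Neither value can be read against 0 as evidence of agreement, and the distance from the simulated ranges was not tested. Leaving out each mouse gave 6 (control diet vehicle mouse 1) to 66 (mouse 5) genes for VB on the control diet, 605 to 1225 on the Western diet, 1663 to 2411 for diet in vehicle mice, 541 (without control diet VB mouse 4) to 720 in VB mice, 665 to 1702 (without Western diet vehicle mouse 4) for the difference and 0 to 65 (without Western diet VB mice 2 and 4) for the mean. The correlations ran from -0.31 to -0.21, 0.21 to 0.31 and -0.68 to -0.60.

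With the mouse number as a replicate block the counts were 65 for VB on the control diet, 1067 on the Western diet, 2312 and 973 for diet in vehicle and VB mice, 1146 for the difference and 66 for the mean. All of these were above the counts of the reported fit. Mice of the same number correlated in their deviations at 0.04, 0.10, 0.02 and 0.05 on average over the 4 comparisons of 2 groups. Not each pair passed 0.1, and not every mouse correlated best with its own number, so a full pairing was not seen. A partial pairing by number stays open.

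Sign changes were counted only for genes and lists called in the reported fit. With the clock score as a covariate 43 such values changed sign. For VB on the control diet these were Npas2 (0.26) and the lists of fatty acid oxidation (-0.0666), carnitine (-0.0898), PPARA targets (-0.21), amino acid catabolism (-0.12), glucocorticoid response (-0.20) and male-biased genes (0.21), and on the Western diet the acute phase list (0.0783). For diet in vehicle mice they were Bbox1 (-0.16), Slc22a5 (-0.0441), Cpt2 (-0.0625), Fgf21 (-0.78), Cd36 (-0.0752), Dbp (-1.20), Acot3 (-1.58), Hadh (-0.29), Slc25a20 (-0.22), Bdh1 (-0.47), Slc27a1 (-0.11), Cyp3a59 (-0.16), Mt1 (-1.79), Rps9 (0.0253), Cyp2a4 (-0.39), Cyp2b9 (-2.57), Cyp2e1 (-0.30), Cd9 (0.0224), S100a9 (-3.14), Ighm (0.30) and Sox9 (0.0585). Their lists were fatty acid oxidation (-0.13), carnitine (-0.11), PPARA targets (-0.12), endoplasmic reticulum stress (0.13), acute phase (-0.31), clock (-0.16), ribosomal (0.0179), male-biased (0.45) and female-biased (-0.78). For the difference they were Bbox1 (0.0037) and the xenobiotic (0.28), acute phase (0.27) and clock (0.0336) lists, and for the mean amino acid catabolism (-0.0146). The others were oxidative phosphorylation for diet in VB mice with a surrogate variable (-0.0634) and, for the mean, amino acid catabolism with quality weights (-8.9e-04), the adipose list with no filter (0.82) and oxidative phosphorylation without Western diet vehicle mouse 4 (0.0042). Npas2, Dbp and the clock list make up the clock score, so their turns with it carry little weight. The other turns for diet in vehicle mice are uncertain too. The vehicle groups did not overlap in the score, and with it the median SE of the 2083 genes went from 0.14 to 0.43.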

Other observations

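The tests in this part were fixed before the data were examined, and Slc9a9 was singled out after its values were seen. Lists of macrophages, monocytes and neutrophils, T and NK cells, B cells, endothelial cells, stellate cells, bile duct cells and red blood cells were not called for VB on either diet. In VB mice the Western diet lowered 3 of 21 stellate genes, also 3 when adjusted over the list alone, and 1 of 16 endothelial genes, also 1 when adjusted over the list alone (adjusted p = 0.698 with an estimated correlation for each).

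Slc9a9 was low in every control diet VB mouse, at 0.14 CPM ± 0.11 (SD, n = 5) against 1.96 ± 0.61 in vehicle mice. On the Western diet it was at 0.53 CPM ± 0.53 in VB mice and 1.56 ± 0.53 in vehicle mice.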
